A study of Mus musculus with 12 samples.

How the data were processed

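The series measured RNA by sequencing in B220+ CD73+ memory B cells of the liver and spleen of mice infected with Ehrlichia muris, sorted as CD11b and CD11c double negative (DN) or double positive (DP). There were 4 groups of 3 libraries, grouped by the sample titles. RNA was extracted with a column kit for small samples and turned into cDNA with a SMARTer low-input kit, per the labels' protocols, and sequenced as 75 bp paired ends on an Illumina NextSeq. Reads were checked with FastQC 0.11.7, trimmed with Trim Galore and cutadapt 1.18, aligned to mm10 with STAR 2.6.1a and counted with featureCounts of Subread 1.6.2, per the submitters' processing notes, which also name limma. The version of the annotation used for counting is not given in the sources used here.

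The deposited values are log2 CPM (counts-per-million) on the scale of voom, quantile normalized by the authors, per the series' design text and from the values themselves. Each library has 23420 genes, of which 4780 have 1 value in all 12 libraries. The log2 value of a zero count, -5.34, corresponds to a library of 20.3 M counts. Whole counts per gene were not used here, because normalization removed them, and no counting interval is given for single values.

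The values also carry an adjustment along the replicate number that the labels do not mention. For all 23420 genes the mean over the 4 libraries numbered 1 and the mean over the 4 numbered 3 differed by less than 0.001 (log2), with a largest difference of 0.00075. Among 13067 tested genes the means of the libraries numbered 1 and 2 had a median difference of 0.206, and the lowest median difference over other pairings of libraries was 0.102. Of 2111 genes at the floor in the 4 libraries numbered 2 and varying elsewhere, 2082 had their lowest number 1 and number 3 values mirrored about the floor within 0.002. Differences between groups with all 3 libraries are not moved by such an adjustment, while the spread within groups is reduced and 1 degree of freedom is used up. Values below the floor in single libraries come from it.

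A voom fit on counts had been planned before the data were examined, with the gene lists, the comparisons, the gene filters and the rule for named genes. Because the values are normalized log2 values, limma 3.58.1 in R 4.3.3 was used on them instead, with a mean-variance trend, the 4 group means and a centred term for the replicate number, which left 7 residual degrees of freedom in place of 8. The term was chosen after the data were seen. Adjusted p-values are limma's with Benjamini-Hochberg adjustment at 0.05, and fold changes are differences of group means on the log2 scale. No pseudocount was added to the deposited values.

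The comparisons of DP with DN in each organ, and the difference between them, used the 13067 genes at the level of at least 10 counts (log2 -0.95) in at least 3 libraries. The comparisons of liver with spleen used the 9685 genes at the level of at least 30 counts (log2 0.59) in all 12 libraries, the filter that the design text gives because of liver cell transcripts. Gene lists were tested with limma's rank sum test that allows for an estimated correlation between genes, as named in the design text. Members below the 30-count filter were tested for the lists of other cell types in all comparisons. Lists with fewer than 5 measured members were not tested. Summed linear values of the lists of other cell types were compared by exact permutation tests, two-sided, whose smallest p for 3 against 3 is 0.1, with Benjamini-Hochberg adjustment over the lists and comparisons. Genes were placed on mm10 with GENCODE M21, in which 21737 symbols matched directly and 1272 through an older symbol. The counting is not stated to have used strand, so overlapping genes on opposite strands cannot be told apart.

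On simulated data with 200 changed genes, the test of spleen DP against DN over 13067 genes recovered 52% of genes changed by log2 1 and 67% of those changed by log2 2, with 5.56% of the calls false, against 11.1% without the replicate number term. The test of liver against spleen DN over 9685 genes recovered 71% and 94%, with 4.07% false. The test of the difference between organs over 13067 genes recovered 28% and 52%, with 6.98% false. A shifted list of 20 genes was called in 100% of 50 draws and an unshifted one in 0%, by the list test's unadjusted p under 0.05. The simulated genes were independent. In spleen DP against DN the estimated correlation was 0.123 for the T-bet and CD11c list and 0.867 for the cell cycle list. These shares therefore do not give the power for the real lists, and a list that did not pass is not shown to be unchanged.

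Named genes followed a rule fixed in advance. It takes 10 genes always reported (Itgam, Itgax, Ptprc, Nt5e, Tbx21, Zeb2, Cxcr3, Cr2, Fcer2a and Bach2) and the 12 highest and 12 lowest passing genes with no overlap of libraries and at least 5 CPM in the higher group, or 6 each for the difference between organs. It adds up to 4 members of each list by adjusted p and 3 members of each list of another cell type by level. The planned scaled CPM of this rule was replaced by the deposited value. The text names part of the genes the rule gives, and some results are not reported here.

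The labels give the groups the same replicate numbers and do not say that a number marks a shared animal or day. Of 18 pairs of libraries with the same number, 9 had a correlation of deviations from the group means over 0.1. The range was -0.22 to 0.25 for number 1, 0.15 to 0.38 for number 2 and -0.43 to 0.2 for number 3. The adjustment along the replicate number acts on the libraries numbered 1 and 3, so their correlations cannot show whether the numbers pair the libraries. The main fit did not take the numbers to pair the libraries, and this stays undecided. For the spleen groups alone all 3 pairs were over 0.1, and the fit with the replicate number as a block is given beside that comparison. Alternatives covered the replicate number, gene filters, library weights, the groups fitted, a minimum fold change of 2, the correlation of the list test and each library left out. The variance trend, a pseudocount of 1 CPM, the floor, centring the omission of the liver libraries numbered 3 and the T-bet and CD11c list without the sort markers were added after the data were seen. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.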

Results

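RNA was sequenced from memory B cells of C57BL/6 mice after infection with Ehrlichia muris, an intracellular bacterium that infects mice. B cells carrying B220 and CD73, the latter an ecto-nucleotidase found on many memory B cells, were sorted from liver and from spleen into cells lacking both CD11b and CD11c (double negative, DN) and cells carrying both (double positive, DP). The 4 groups, liver DN, liver DP, spleen DN and spleen DP, had 3 libraries each, 12 in all. Each library had gene values on a log2 counts-per-million (CPM) scale that the authors had normalized, so read totals per library are not used here. The labels do not say whether the libraries of a group came from separate mice, so p-values measure the spread between these libraries. The first principal component held 48.5% of the variance and separated the organs, and the second held 22.4% and separated DP from DN.

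The sort markers followed the labels in every library. Itgam, which encodes CD11b, had a linear value of 158 ± 38.2 CPM in spleen DP and 3.68 ± 1.25 CPM in spleen DN, and 179 ± 50.1 CPM in liver DP against 4.47 ± 4.03 CPM in liver DN (mean ± SD, n = 3 each). Itgax, which encodes CD11c, had 383 ± 197 CPM in spleen DP, 2.76 ± 0.973 CPM in spleen DN, 55.8 ± 27.4 CPM in liver DP and 0.683 ± 0.447 CPM in liver DN, where 1 library lay below the level of 10 counts. Both genes lie on mouse chromosome 7 in the mm10 build, Itgam at 128062640 to 128118491 and Itgax at 128129547 to 128150657, both on the plus strand. Ptprc, the gene of the B220 isoform of CD45, lay between 1320 and 1920 CPM in the 4 groups and passed the test in none of the 4 comparisons.

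**Figure D1:**
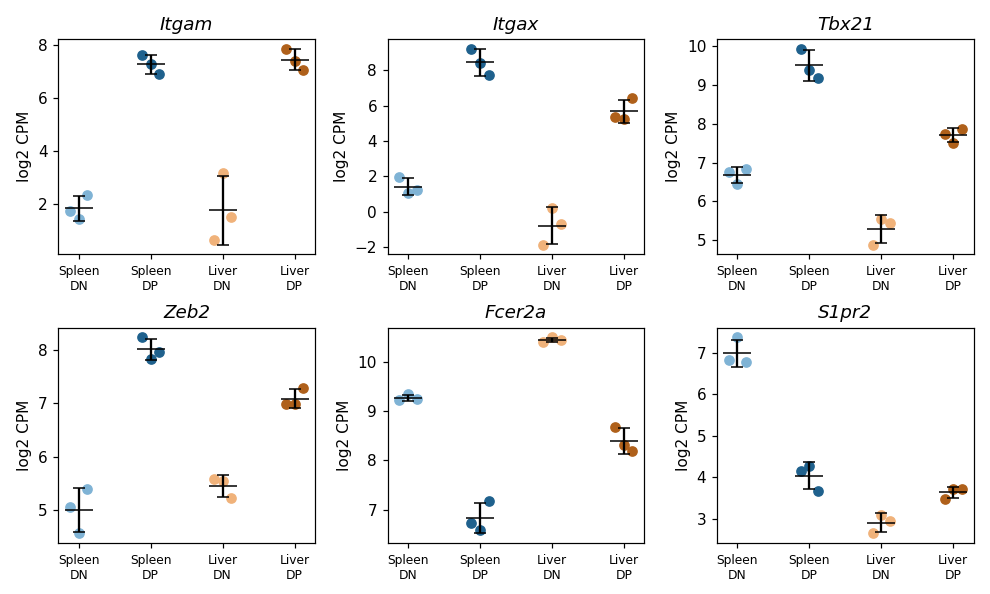
Deposited log2 CPM (y axis) of 6 genes in each of the 12 libraries by group (x axis), with points for libraries and bars for the mean and SD of 3. Itgam, Itgax, Tbx21 and Zeb2 lie higher in DP than in DN in both organs, Fcer2a lies lower, and S1pr2 stands highest in spleen DN.

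The first comparison asked how CD11b and CD11c double positive memory B cells of the spleen differ from double negative ones. Spleen DP cells had higher RNA of Tbx21 and of most T-bet-linked genes measured, and lower RNA of most germinal centre genes measured, though neither list passed the list test (list adjusted p = 0.376 and 0.547 with an estimated correlation). Tbx21, which encodes the transcription factor T-bet, rose by 2.82 ± 0.22 on the log2 scale (± SE, limma adjusted p = 3.35e-05), from 104 ± 14.3 to 747 ± 210 CPM, and lies on the minus strand of chromosome 11 at 97098071 to 97115331. Zeb2, a transcription factor linked to CD11c-positive B cells, rose by 3.0 ± 0.20 (limma adjusted p = 1.87e-05). Fcer2a, the gene of the low-affinity IgE receptor CD23 of follicular B cells, fell by 2.44, from 620 ± 25.7 to 116 ± 26 CPM. Of 13067 genes tested, 1222 had a limma adjusted p under 0.05, 767 higher and 455 lower in DP.

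Of the 20 measured genes of the T-bet and CD11c list, 14 rose and none fell in spleen DP, with 16 rising and 1 falling when adjusted over the list alone (list adjusted p = 0.376 with an estimated correlation). The sort markers Itgam and Itgax are 2 of these members. Without them, an alternative chosen after seeing the data, 12 of 18 rose (14 rising and 1 falling adjusted over the list alone, list adjusted p = 0.42 with an estimated correlation). Those that rose included Lgals3 (2.36), a galectin, besides Tbx21 and Zeb2. Macrophages express some of these members too, Lgals3 among them, and the summed macrophage list was 28.2-fold higher in the same comparison. Among other summed lists, those of monocytes (4.32-fold), NK cells (2.04-fold) and neutrophils (18.5-fold) were higher too, and that of T cells lower (0.252-fold, exact permutation p = 0.1 each). Whether the rises and falls in this list and the following ones came from the B cells was not tested. Of the 19 genes of the inhibitory receptor list, which also holds phosphatases acting downstream of such receptors, 6 rose and 2 fell (7 and 4 adjusted over the list alone, list adjusted p = 0.556 with an estimated correlation), among them Fcgr2b (1.51), the inhibitory IgG receptor, and Cd72 (1.39), which rose, and Cd5 (-1.87), which fell. Of this list 1 fell without spleen DN library 1 or 3 or spleen DP library 1. Of the 15 genes of the Toll-like receptor sensing list, which also holds adaptors, cofactors and signalling genes, 4 rose (8 adjusted over the list alone, list adjusted p = 0.547 with an estimated correlation), with Tlr7 at 1.02 and Tlr9, the receptor of unmethylated DNA, at 1.31. Lists overlap, so their counts are not separate: Tlr7, Tlr9, Itgb1 and Zbtb32 are also members of the T-bet and CD11c list. Cd5 belongs to both the inhibitory receptor and the B-1 cell lists. Of the 13 follicular and naive B cell genes, 4 fell (5 adjusted over the list alone, list adjusted p = 0.556 with an estimated correlation), and 2 fell without spleen DP library 1. Of 23 trafficking genes 6 rose and 3 fell (8 and 3 adjusted over the list alone, list adjusted p = 0.556 with an estimated correlation). S1pr5, a receptor for sphingosine-1-phosphate, rose by 5.39 and the integrin gene Itgb1 by 1.62, while Cxcr5, the chemokine receptor of B cell follicles, changed by -0.59 and did not pass without spleen DP library 1 (limma adjusted p = 0.0518). Of 11 memory B cell genes 3 rose and 1 fell (5 and 1 adjusted over the list alone, list adjusted p = 0.547 with an estimated correlation), Cd38 (1.38) and Zbtb32 (1.54) rising and Cd27 (-2.08) falling, which did not pass without spleen DN library 1 (limma adjusted p = 0.0636). Of 9 B-1 cell genes 5 rose and 3 fell (5 and 3 adjusted over the list alone, list adjusted p = 0.558 with an estimated correlation), with Bhlhe41 (1.98), a regulator of B-1 cells, among those that rose and Cd5 among those that fell, and 1 fell without spleen DP library 1 or 3.

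Germinal centre genes fell in spleen DP. Of 12 measured, 10 fell and 1 rose (10 and 1 adjusted over the list alone, list adjusted p = 0.547 with an estimated correlation), and 6 fell without spleen DP library 1. S1pr2, which retains B cells in germinal centres and lies on chromosome 9 at 20962361 to 20976781, had 129 ± 31.6 CPM in spleen DN and 16.7 ± 3.52 CPM in spleen DP (log2 -2.95 ± 0.22, limma adjusted p = 3.35e-05). Mef2b changed by -4.39 and Rgs13 by -4.41. T cell genes moved with them: 13 of 14 fell in spleen DP (14 adjusted over the list alone, list adjusted p = 0.13 with an estimated correlation), with Lck, a T cell receptor kinase, at -2.10, and their summed value was 975 ± 154 CPM in spleen DN and 246 ± 44.3 CPM in spleen DP (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allow, Benjamini-Hochberg adjusted 0.208). Id3 (-2.10), an inhibitor of E proteins, Cd55 (-1.32) and Bach2 (-0.97), a repressor of plasma cell fate, fell as well, though Bach2 no longer passed without spleen DP library 1 (limma adjusted p = 0.0544) or with the spleen libraries alone (0.0816). The sterol synthesis genes Fdps (-1.24) and Sqle (-1.13) fell.

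Myeloid genes stood among the largest rises in spleen DP. Of 14 macrophage genes 12 rose (13 adjusted over the list alone, list adjusted p = 0.13 with an estimated correlation) and of 12 monocyte genes 9 rose (11 adjusted over the list alone, list adjusted p = 0.0339 with an estimated correlation). Lyz2, lysozyme, rose by 7.14 ± 0.41, Emr1, the F4/80 gene, by 5.04 ± 0.19, and Csf1r, the macrophage growth factor receptor, by 5.57 ± 0.63. The summed macrophage list reached 1640 ± 483 CPM in spleen DP and 58.1 ± 16.8 CPM in spleen DN (exact permutation p = 0.1). Among the highest log2 changes outside the marker lists were those of Megf10 (7.90), Lpar3 (7.61), Slamf8 (7.48), Ace (7.47) and Tlr13 (7.33). Megf10 and Ace lay below the level of 10 counts in every spleen DN library, so the sizes of their changes depend on the floor of the values.

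With the replicate number as a block 1964 genes passed in the spleen comparison, and spleen DN and DP libraries of the same number deviated from their group means together, with correlations across genes of 0.25, 0.37 and 0.2. The labels do not say that a number marks a shared animal. The adjustment along the replicate number acts on the libraries numbered 1 and 3, so their correlations (0.25 and 0.2) cannot show pairing. The count of 1222 was 541 without spleen DP library 1, 667 without spleen DN library 2, 730 without spleen DN library 1 and 784 when the liver libraries were left out of the fit.

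The same comparison in the liver asked how DP and DN memory B cells of that organ differ. Liver DP cells again had higher Tbx21 (2.42 ± 0.22, limma adjusted p = 0.000112), from 39.7 ± 8.97 to 210 ± 25.9 CPM, and lower Fcer2a (-2.06 ± 0.16), from 1400 ± 46.6 to 340 ± 62.5 CPM. Zeb2 rose by 1.63, Cxcr3, a chemokine receptor induced by T-bet, by 2.11, and Nt5e, the CD73 gene, by 1.40. Of 13067 genes tested, 853 had a limma adjusted p under 0.05, 615 higher and 238 lower in DP.

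Of the 20 T-bet and CD11c genes 17 rose in liver DP and none fell (18 adjusted over the list alone, list adjusted p = 0.118 with an estimated correlation), and without the sort markers Itgam and Itgax, again chosen after seeing the data, 15 of 18 rose (16 adjusted over the list alone, list adjusted p = 0.114 with an estimated correlation). They included Itgb1 (2.24) and Lgals3 (2.20), beside a summed macrophage list 7.37-fold higher in liver DP. Of 9 B-1 cell genes 7 rose (7 and 1 falling adjusted over the list alone, list adjusted p = 0.449 with an estimated correlation), with Anxa2, an annexin, at 2.37, Tppp3 at 4.26 and Spn, the CD43 gene, at 1.81. Of 13 follicular and naive genes 7 fell (9 adjusted over the list alone, list adjusted p = 0.449 with an estimated correlation), among them Cd55 (-1.05), and 4 fell without liver DN library 1, without liver DN library 3 or without both liver libraries numbered 3. S1pr5 rose by 4.75, Cx3cr1 by 4.68 and Fcgr2b by 1.32, while Bcl6, the germinal centre repressor, changed by -1.18. The summed monocyte and NK cell lists were 5.77-fold and 3.05-fold higher in liver DP (exact permutation p = 0.1 each). Whether the rises in the lists above and those of S1pr5, Cx3cr1 and Fcgr2b came from the B cells was not tested. With the liver libraries alone Cx3cr1 did not pass (limma adjusted p = 0.0504). Of 12 germinal centre genes 1 rose and 1 fell in liver (2 and 2 adjusted over the list alone, list adjusted p = 0.995 with an estimated correlation), and 3 fell without liver DP library 2.

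Monocyte and macrophage genes were higher in liver DP too. Of 12 monocyte genes 9 rose (10 adjusted over the list alone, list adjusted p = 0.0365 with an estimated correlation), and 6 rose without the liver libraries numbered 3, an alternative chosen after seeing the data. Of 14 macrophage genes 8 rose (12 adjusted over the list alone, list adjusted p = 0.279 with an estimated correlation), 2 without liver DN library 1, 3 without liver DN library 2, liver DP library 1 or liver DP library 3, and 5 without both liver libraries numbered 3. Lyz2 rose by 4.57 ± 0.41 to 1080 ± 599 CPM and Emr1 by 3.42 ± 0.19. The summed macrophage list had 1010 ± 449 CPM in liver DP and 138 ± 55.9 CPM in liver DN (exact permutation p = 0.1), and the neutrophil list 84.1 ± 87 CPM and 1.96 ± 1.57 CPM. Liver DP library 3 had the highest neutrophil sum, 181 CPM against 13.9 and 57 CPM in libraries 1 and 2, and the mean was 35.5 CPM without it. In liver DN the neutrophil mean was 1.06 CPM without library 1. Perforin, encoded by Prf1 and used by NK and cytotoxic T cells, rose by 2.10, and the summed NK cell list had 298 ± 120 CPM in liver DP and 97.6 ± 30.4 CPM in liver DN. The highest log2 changes outside the marker lists were those of Ace (8.42), which lay below the level of 10 counts in every liver DN library, and Tlr13 (7.32), while Tmem108 (-3.06), a membrane protein gene, fell. The count of 853 was 431 without liver DN library 1, 260 when the spleen libraries were left out of the fit and 1419 with the replicate number as a block.

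**Figure D2:**
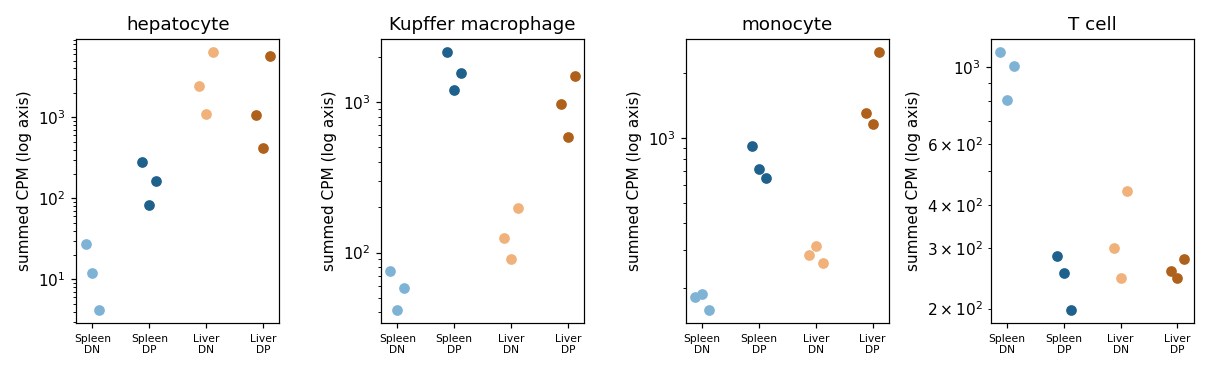
Summed linear values (y axis, CPM, log axis) of 4 marker lists of other cell types in each of the 12 libraries by group (x axis). The macrophage list is higher in DP than in DN in both organs, the T cell list is highest in spleen DN, and the hepatocyte list is highest in the liver groups.

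Hepatocyte RNA was present in the liver libraries. The 22 hepatocyte genes summed to 3320 ± 2780 CPM in liver DN and 2380 ± 2860 CPM in liver DP, against 14.6 ± 12 CPM in spleen DN and 176 ± 98.5 CPM in spleen DP (n = 3 each). The 2 liver libraries numbered 3 had the highest sums, 6430 CPM in DN and 5660 CPM in DP, and without them the means were 1760 CPM in DN and 745 CPM in DP. In spleen DN the mean was 8.04 CPM without library 1. The liver and spleen comparisons therefore used the 9685 genes at the level of 30 counts or more in all 12 libraries, the filter that the series' design text sets against liver cell RNA.

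Across 13067 genes, the DP minus DN changes of liver and spleen had a Pearson r of 0.55, a Spearman rho of 0.35 and a covariance of 0.549, and genes are not independent replicates. Of the genes called, 354 were higher in DP in both organs, where independent lists would share 36.1, and 91 were lower in both, where independent lists would share 8.29. The direction was opposite for 5. The comparisons share no library, but they used the same estimate of the spread for each gene. Genes with a low spread could therefore pass in both more often than independent lists would. The summed macrophage list was higher in DP in both organs (28.2-fold in spleen, 7.37-fold in liver), as was the monocyte list (4.32-fold and 5.77-fold). Whether RNA of such cells makes up part of the shared higher genes was not tested.

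**Figure D3:**
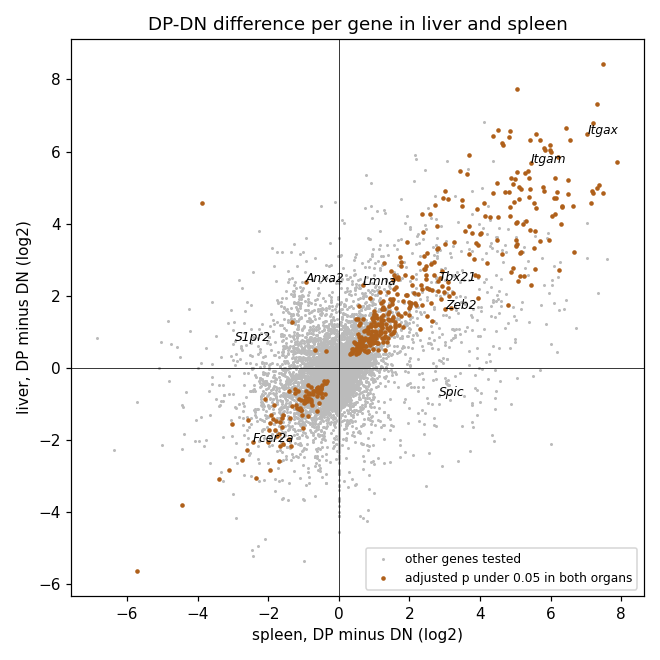
DP minus DN difference (log2) of each of 13067 genes in spleen (x axis) and liver (y axis). Points in brown passed the test in both organs, 354 of them higher and 91 lower in DP in both.

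The test of the difference between the organs' DP minus DN changes called 21 genes, 17 with a more positive change in liver and 4 with a more negative one, and 1655 genes had an unadjusted p under 0.05. S1pr2 differed by 3.69 ± 0.31 (limma adjusted p = 0.00115): it fell in spleen DP, and in liver its value was 7.52 ± 1.15 CPM in DN and 12.5 ± 1.13 CPM in DP. Anxa2 differed by 3.31 ± 0.29 (limma adjusted p = 0.00115), with 466 ± 118 CPM in liver DP and 186 ± 26.2, 97.6 ± 18.1 and 89.1 ± 16.6 CPM in spleen DN, spleen DP and liver DN. Of the genes always reported, Tbx21 (-0.40, limma adjusted p = 0.607), Zeb2 (-1.37, limma adjusted p = 0.0959) and Fcer2a (0.38, limma adjusted p = 0.501) did not pass. This count depended on single libraries: it was 3, 6 and 13 without liver DN libraries 1, 2 and 3, and 4, 6 and 63 without liver DP libraries 1, 2 and 3. It was 2 and 7 without spleen DN libraries 1 and 2, and 4, 6 and 9 without spleen DP libraries 1, 2 and 3. With the replicate number as a block 331 genes passed.

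The comparison of liver with spleen within DN cells asked how memory B cells without CD11b and CD11c differ between the organs. Most immediate early genes measured were higher and the cell cycle genes measured were lower in liver DN than in spleen DN, though neither list passed the list test (list adjusted p = 0.152 and 0.584 with an estimated correlation). Nr4a1, an orphan nuclear receptor gene induced by antigen receptor signals and located on chromosome 15 at 101254269 to 101274795, rose by 4.47 ± 0.33 (limma adjusted p = 3.42e-05), from 30.5 ± 5.74 to 712 ± 292 CPM, and Cd69, an activation and retention receptor, rose by 2.34 ± 0.14, from 92.5 ± 13.8 to 466 ± 25.1 CPM. S1pr2 fell by 4.09 and S1pr3, a receptor of marginal zone B cells, by 4.26. Of 9685 genes 1773 had a limma adjusted p under 0.05, 759 higher and 1014 lower in liver.

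Of 15 immediate early and heat shock genes 13 rose in liver DN (14 adjusted over the list alone, list adjusted p = 0.152 with an estimated correlation), and 8 rose without liver DN library 1. They included Klf6 (1.88), Egr1 (1.98) and the heat shock gene Hspa1a (5.20), which no longer passed without liver DN library 1 (limma adjusted p = 0.0572), liver DN library 2 (0.0676), spleen DN library 1 (0.0955) or spleen DN library 3 (0.0628). All 20 measured cell cycle genes fell (20 adjusted over the list alone, list adjusted p = 0.584 with an estimated correlation), among them Plk1 (-3.80), a mitotic kinase, and Tk1 (-1.66), thymidine kinase. Of 9 marginal zone genes 6 fell (7 falling and 1 rising adjusted over the list alone, list adjusted p = 0.436 with an estimated correlation), with Dtx1, a Notch target, at -1.72 and Cd9 at -1.03. Of 6 recirculation genes 4 rose (5 adjusted over the list alone, list adjusted p = 0.436 with an estimated correlation), including Ccr7 (1.94), the receptor for entry into lymph nodes. Fcer2a (1.18) and Cd55 (1.66) were higher in liver, and Tbx21 (-1.40), Cxcr3 (-1.39) and Tlr3 (-3.72), a receptor of double-stranded RNA, were lower. T cell genes were lower in liver DN too, 12 of 14 passing the test (13 adjusted over the list alone, list adjusted p = 0.549 with an estimated correlation), with a summed value of 328 ± 100 CPM against 975 ± 154 CPM. Serpinc1 (4.36), antithrombin made by hepatocytes, was among the highest genes beside the hepatocyte RNA of these libraries. The count of 1773 was 662 without liver DN library 1, 803 without spleen DN library 2, 883 without spleen DN library 1 and 2693 with the replicate number as a block.

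The comparison of the organs within DP cells asked how the CD11b and CD11c double positive cells differ between liver and spleen. Liver DP cells shared the higher Nr4a1 (3.65 ± 0.33) and Cd69 (2.65 ± 0.14, limma adjusted p = 3.43e-06) and had lower Tbx21 (-1.81 ± 0.22, limma adjusted p = 0.000907), 210 ± 25.9 CPM against 747 ± 210 CPM. Lmna, which encodes the nuclear lamins A and C and lies on chromosome 3 at 88480147 to 88509956, rose by 3.36 ± 0.17, from 16.1 ± 2.98 CPM in spleen DP to 164 ± 15.9 CPM in liver DP. Of 9685 genes 694 had a limma adjusted p under 0.05, 368 higher and 326 lower in liver.

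Of 15 immediate early and heat shock genes 11 rose in liver DP (14 adjusted over the list alone, list adjusted p = 0.129 with an estimated correlation), with Klf6 at 2.09, Egr1 at 1.97 and Dusp1, a phosphatase gene, at 2.35. The 20 cell cycle genes had a median change of -0.35, and none passed the test (list adjusted p = 0.849 with an estimated correlation). Of 8 B-1 cell genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, list adjusted p = 0.721 with an estimated correlation): Anxa2 (2.24), Zbtb32 (1.85) and Ctla4 (2.77), an inhibitory receptor, rose and Bhlhe40 (-1.18) fell, and Ctla4 did not pass with the DP libraries alone (limma adjusted p = 0.0615). Il5ra (2.92), the interleukin 5 receptor, S100a6 (2.65), a calcium-binding protein gene, and Itgb7 (1.82), an integrin of gut homing, were higher in liver. Tlr3 (-3.92), S1pr3 (-3.54), Dtx1 (-2.08), Cr2 (-1.73), the complement receptor of marginal zone and follicular cells, and Cd72 (-1.61) were lower. RNA of the macrophage list was present in both DP groups, 1010 ± 449 CPM in liver and 1640 ± 483 CPM in spleen by the summed list (exact permutation p = 0.2). The summed monocyte list was higher in liver DP, 1660 ± 741 CPM against 760 ± 140 CPM in spleen DP (exact permutation p = 0.1).

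Across 9685 genes, the liver minus spleen changes of DP and DN cells had a Pearson r of 0.54 and a Spearman rho of 0.51. Of the genes called, 224 were higher in liver in both subsets, where independent lists would share 28.8, 162 were lower in both, where they would share 34.1, and 6 went opposite ways. Both comparisons again used the same estimate of the spread for each gene, so the calls are not independent. The count of 694 in DP cells was 233 without spleen DP library 1, 387 without liver DP library 1, 447 without spleen DP library 2, 456 without spleen DP library 3, 141 when only the DP libraries were fitted and 1332 with the replicate number as a block. It was 1118 with the gene filter of the DP and DN comparisons, which tests more genes.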

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

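All tests of explanations in this part were chosen only after the results were seen, and the test of the difference between organs by shuffling took its form after an earlier form had been run. That earlier form set a fit with the replicate number term against shuffles fitted without it and was replaced because the fits differed. The rule for a tissue residency program was changed after a first form, which rested on recirculation genes alone and excluded it, had been run, as were the rule for RNA of macrophages, first set against random lists alone, and that for T cell RNA in spleen DN, first without the pairs of libraries of the same number.

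A test of the difference between the DP minus DN changes of liver and spleen singled out 21 genes. The change was more positive in liver for Rab44 (8.44), Nbl1 (4.72), Rassf6 (4.06), S1pr2 (3.69), Anxa2 (3.31), Rtn4rl1 (2.58), Emb (2.53), S100a6 (2.19), 8430410A17Rik (2.02), Slfn1 (2.01), Cdh17 (1.87), Lmna (1.61), Neil1 (1.55), Fxyd5 (1.16), Smpdl3a (1.11), Bid (0.84) and Bzw2 (0.82), all on the log2 scale. Mean log2 values of Rab44 were -4.69 in liver DN and -3.98 in spleen DP, and that of Nbl1 was -2.26 in liver DN. These lie below the level of 10 counts (-0.95), so the sizes of these differences depend on the floor of the values. The DP minus DN change was more negative in liver for Cd72 (-1.06), Ms4a4c (-1.15), Emr1 (-1.62) and Spic (-3.62). Emr1 and Spic are members of the macrophage list, whose sum was 28.2-fold higher in DP in spleen and 7.37-fold higher in liver. Whether the differences of the 21 genes came from the B cells was not tested. When the residuals were shuffled within each replicate number, 2 of 100 orders, the real one included, called as many genes, and 98 of the 99 shuffles called none. The highest other order called 82 genes, several times the real 21, which may reflect a structure of the libraries that was not traced further. Shuffled over all 12 libraries, 4 of 100 orders called as many and the highest called 968. These shares make a chance order less likely but do not exclude it, since the form of the test was chosen after the results were seen. The count ranged from 2 to 63 when single libraries were left out. Under all alternatives run S1pr2 and Anxa2 passed, while the other 19 genes each lost their call under at least 1, with 208 lost calls in 572 values of the genes named for this difference.

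For each of the other comparisons the 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. In each of them 1 split, the real one, called as many genes. The real splits called 1222 genes between spleen DP and DN, 853 between liver DP and DN, 1773 between liver and spleen DN and 694 between liver and spleen DP, and the highest other split called 0 in each.

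Of 14 macrophage genes 12 were higher in DP than in DN in spleen and 8 in liver, 2 there without liver DN library 1, though the list did not pass the list test (list adjusted p = 0.13 and 0.279 with an estimated correlation). Explanations are RNA of macrophages in the DP libraries, which the sort on B220 should have removed but which carry CD11b and CD11c themselves, and a myeloid program of the DP B cells. The macrophage list moved together across the DP libraries: the SD of its mean was 0.746 in liver DP and 0.652 in spleen DP against medians of 0.114 and 0.0845 in random lists of like level, at percentile 100 in both, but lists of B cell programs reached 0.841 and 0.887, so this spread does not separate RNA of macrophages from a program of the cells. Of 14 members 7 lay apart by over 2-fold between liver DP and spleen DP. Of these, 3 were higher in liver, among them Clec4f (12.54), at the floor in spleen DP, and Vsig4 (7.53). Another 4 were higher in spleen, among them Vcam1 (-5.07) and Spic (-3.09). The DN libraries were not subtracted, so this cannot decide whether a myeloid program is alike in both organs. Between liver DN and spleen DN, 5 of the 14 were higher in liver and 1 lower. Of 12 monocyte genes 9 rose in DP in each organ. Between liver DP and spleen DP 1 of the 12 was higher in liver and 0 lower. RNA of macrophages and a myeloid program, alike in both organs or not, stay open.

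Cd69 was higher in liver in both subsets, as were 13 of 15 immediate early and heat shock genes in DN, 8 without liver DN library 1, and 11 in DP, though the list did not pass the list test (list adjusted p = 0.152 and 0.129 with an estimated correlation). A tissue residency program would lower recirculation genes, but their median liver minus spleen difference was 0.972 in DN and 0.494 in DP. Of 10 residency genes 4 rose and 1 fell in each subset, among the 4 Cd69 and Nr4a1 of the pattern itself, and in DP 2 rose when any 1 spleen DP library was left out, so a residency program stays open. Of the heat shock genes Hspa1a, Hspa1b and Dnajb1, 3 rose in liver DN and 2 in liver DP. In DN, Hspa1a no longer passed without liver DN library 1 or 2 or spleen DN library 1 or 3. These genes are members of the list of the pattern itself, so their rise is no separate test of handling or heat stress. Handling or heat stress of the liver samples stays a candidate explanation. Organ and handling are confounded, so a response of the cells in the liver itself stays open.

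Of 12 germinal centre genes 10 were higher in spleen DN than in spleen DP, 6 without spleen DP library 1, though the list did not pass the list test (list adjusted p = 0.547 with an estimated correlation). Without any 1 spleen DN library the median change of the list was -2.61 or lower, which argues against a single library. The germinal centre list fell by 0.61 (log2) more than the T cell list, with overlap of the libraries, and by 0.46, 1.07 and 0.29 more in the spleen pairs of the same number, so T cell RNA in the spleen DN libraries, follicular helper T cells among its sources, stays open as part of it. The germinal centre mean minus the T cell mean was -0.35 to 0.78 in spleen DN and -2.31 to -0.64 in liver DN, so T cell RNA did not carry a fixed share of germinal centre RNA in both organs. Germinal centre B cells within the spleen DN gate stay open as the biological explanation.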

How the results depend on the processing

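Of 115 single-gene results, 2281 alternative values gave 2056 with the same direction and side of the threshold, 220 that no longer passed, 5 that newly passed and 0 that turned direction. Of the 220, 208 belonged to the difference between organs, among 572 values there, and 6, 1, 4 and 1 to spleen DP against DN, liver DP against DN, and liver against spleen in DN and DP. Without the replicate number term 83 genes passed in the difference between organs. With the replicate number as a block, the counts were 1964 for spleen DP against DN, 1419 for liver DP against DN, 2693 and 1332 for liver against spleen in DN and DP, and 331 for the difference, and 4 of 12 libraries had a best partner in another group with their own number. Library weights gave 5976, 3902, 5860, 4312 and 3831 in the same order; the weights did not converge, favoured the libraries numbered 1 (3.2 to 6.55) and called up to 5039 genes in mixed splits of the libraries, so these counts are not reliable. Fitting only the groups compared gave 784, 260 and 141 for spleen DP against DN, liver DP against DN and liver against spleen DP, with fewer libraries behind the spread. A change of at least 2-fold gave 715, 534, 482 and 253 in the 4 comparisons. The other gene filter gave 1118 genes for liver against spleen DP, with more genes tested, and r 0.77 between the liver minus spleen changes. In the difference between organs, 13 genes passed with every gene above the floor, 11 without the variance trend, 38 with a pseudocount of 1 CPM and 55 without the liver libraries numbered 3, where r of the DP minus DN changes was 0.45. The cause was not tested for the other settings. A preset correlation of 0.01 called 9, 10, 8, 7 and 9 lists of B cell programs, against 0 with the estimated one, where limma's unadjusted p was under 0.05 for 2, 1, 2, 1 and 1. Leaving out 1 library gave 541 to 1318 genes in spleen DP against DN, 431 to 1004 in liver DP against DN, 662 to 2040 and 233 to 747 in liver against spleen DN and DP, and 2 to 63 in the difference. The quasi-likelihood and size-factor count tests planned as alternatives were not run, since the values are not counts, nor was scaling by trimmed means, and the difference between organs with only 2 groups is not defined. Depth limits low genes: those under the level of 10 counts in a group have fold changes that depend on the floor.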

Other observations

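Sterol synthesis genes differed between the spleen subsets: 6 of 15 fell in DP (10 adjusted over the list alone, list adjusted p = 0.547 with an estimated correlation), 2 without spleen DN library 1, 3 without spleen DN library 2 and 2 without spleen DP library 3. In liver DP against spleen DP 3 of the 15 rose (7 adjusted over the list alone, list adjusted p = 0.468 with an estimated correlation). Cell cycle genes in liver DP against liver DN had a median change of 1.47, and 0 of 22 passed over all genes (10 rose adjusted over the list alone, list adjusted p = 0.499 with an estimated correlation). Of 25 oxidative phosphorylation genes 7 fell in liver DN against spleen DN (18 adjusted over the list alone, list adjusted p = 0.584 with an estimated correlation), and 1 fell without liver DN library 1 or either of spleen DN libraries 1 and 2, 2 without liver DN library 2, 3 without liver DN library 3 and 12 without spleen DN library 3.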
